A study of Homo sapiens with 3 samples.

How the data were processed

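RNA recovered with an anti-FLAG antibody after crosslinking was sequenced in 3 libraries of K562 cells, 2 with a FLAG-tagged MSI2 vector and 1 with an empty vector, per the labels. Reads were single-end and were aligned with Bowtie2 to the hg19 genome, per the submitters' processing notes; the version, the peak caller, the handling of duplicate reads and the counting rule are not given in the sources used here. Per the file headers, the deposited table holds for each of 30451 peaks its position, strand, gene, feature class and the read count in each library. The read counts of the authors' table are whole numbers and were not normalized, as a check of the values showed. The same table gives the authors' log2 fold change, p-value and adjusted p-value per peak, and a rank score, per the file headers. The test behind the deposited p-values is not named in the sources used here. The deposited adjusted p-values equal a Benjamini-Hochberg adjustment of the deposited p-values over all peaks, and the deposited rank score equals the sign of the fold times the negative log10 of the adjusted p-value. Peaks with equal counts in all libraries differed in the deposited log2 fold (median range 0.54 over 835 groups of equal counts), so the authors' model held a term that the table does not give. The peaks are listed once for all libraries, and each holds at least 16 reads summed over them; how they were selected is not given in the sources used here. The list was not filtered on p-value.

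From the counts, a two-sided quasi-likelihood test was run in edgeR 4.0.16 (R 4.3.3) with TMM scaling and 2 groups, on peaks with at least 10 reads summed over the libraries, which removed none. The TMM factors were 0.882 and 0.962 for FLAG-MSI2 replicates 1 and 2 and 1.179 for the empty-vector library. CPM values use the resulting effective totals of 553668, 699698 and 191023 reads. These totals cover reads in peaks, and the depth outside peaks was not analysed here. With 1 control library the spread of the control is assumed to equal that of the FLAG-MSI2 libraries, and the common biological coefficient of variation was 0.58. Alternatives were the size factors of DESeq2 in the edgeR fit, library totals alone, the Wald test of DESeq2 1.42.0, a minimum of 30 summed reads and a 4-fold minimum.

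The edgeR test was tested on simulated data drawn at the observed means and library sizes with some peaks changed by known folds. The changed peaks were drawn from those with at least 50 summed reads, so the recovered shares do not cover peaks of fewer reads. All peaks had the common dispersion. Most were unchanged (24577 of 24775), which makes the adjusted threshold harder to reach than with many changed peaks. Of 50 peaks made 4-fold higher and 50 made 16-fold higher, 0 and 0 were recovered at an adjusted p below 0.05, and 36% and 94% at an unadjusted p below 0.05. Of 50 peaks made 4-fold lower and 48 made 16-fold lower, 0 and 2 were recovered at the adjusted threshold, and 38% and 93.8% at the unadjusted one. Of unchanged peaks, 5% had an unadjusted p below 0.05. The list test against matched lists was also tested on simulated data. A first list of 60 genes with its odds multiplied by 4 was missed in 1 draw, and in later draws such lists were found at an unadjusted p below 0.05 in 20 of 20 draws with 60 genes and in 11 of 20 draws with 20 genes. The Fisher and the stratified location tests each found a doubled odds of 3′ UTR peaks in 20 of 20 simulated draws, and each called 2 of 20 draws without such an effect. A short list that was not called can therefore still hold such an effect.

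Before the data were examined, the groups, tests, alternatives, 21 gene lists and the rule for named genes were fixed. The rule named MSI2, then among peaks past the threshold and above the control in both replicates the 12 of greatest mean CPM in distinct genes. It added the 12 with the largest fold on CPM + 1 with at least 20 reads in each replicate, up to 4 genes per list, the 6 largest in the other direction, and TGFBR1, SMAD3, NUMB, MYC, HOXA9, IKZF2 and CDKN1A whatever their values. Some items that the rule and the lists include are not reported here. The threshold was an adjusted p of 0.05 in the edgeR test or, where that called no peak, the authors' own p. The second case applied, so higher and lower peaks are those with an adjusted p below 0.05 in the deposited table. The rule allowed for a table filtered on p, and since this one was not filtered, 0.05 was used. In the report, SPN, KLF1, MYB, STAT5B, the further peaks of TMPO and the number of EEF1G peaks fall outside the rule and were chosen after their values were seen. The same holds for genes of the closing part that neither the rule nor the report names.

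Positions are those of the authors' deposited table in hg19. Shares have Wilson 95% intervals, odds ratios have 95% intervals on the log scale with 0.5 added where a cell was 0, and ratios of reads have exact conditional intervals at the effective totals. A fold against 0 control reads is a lower bound at 3 reads, taken per library for the control and over both FLAG-MSI2 libraries for the reverse. This bound takes the reads of the other group as exact, so an exact 95% interval begins lower. Lists were tested by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 20 lists, and against 10000 random lists matched on total reads in 20 bins. The smallest unadjusted p that these random lists can give is 0.0002. Medians of gene lists use the reads summed per gene with 0.5 read added, and were also computed with genes without control reads at their bound of 3 reads. These tests treat genes as units and do not cover the spread between cultures. Python 3.11.15 with scipy 1.17.1 was used.

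A motif test at the peak positions was planned and not run, since an hg19 sequence was not used here. In its place UAG was counted in the longest annotated 3′ UTR of each gene from GENCODE release 29 transcripts, matched on gene identifiers, for 1943 of 2002 genes with a 3′ UTR peak.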

Results

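RNA crosslinked to FLAG-tagged Musashi-2 (MSI2), an RNA-binding protein of blood stem cells and leukaemia, was mapped in K562 cells, an established human chronic myeloid leukaemia line. The assay was HITS-CLIP, in which RNA is crosslinked to protein in cells, recovered by immunoprecipitation and sequenced. The set held 2 libraries from cells with a FLAG-MSI2 vector and 1 library from cells with an empty vector, all precipitated with an anti-FLAG antibody. The table listed 30451 peaks with a median width of 51 bases in 5765 genes, and gave the reads of each library in each peak. FLAG-MSI2 replicate 1 had 627946 reads in peaks, replicate 2 had 727089 and the empty-vector library had 162082. The empty-vector library had no reads at 8686 peaks, against 394 for FLAG-MSI2 replicate 1 and 720 for replicate 2. A count of 0 there allows up to 15.7 CPM, the counts scaled to a common library total, which is the value of 3 reads in that library, and this floor and all intervals on counts cover counting error only.

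The first comparison asked which RNA regions were recovered with FLAG-MSI2 above the empty-vector background. The 3′ UTR of TMPO, which encodes proteins of the nuclear lamina, held 7 peaks, and 6 of them were higher with FLAG-MSI2. The 5 higher peaks of greatest signal in distinct genes lay in RPL8, TMPO, RPS19, EEF1G and RPL18, between 1199 and 1667 CPM. At the other end, coding peaks of the mitotic genes CENPF and NCAPG held 29 and 27 reads in the empty-vector library and 1 read over both FLAG-MSI2 replicates. In the authors' deposited table, 702 peaks in 463 genes were higher with FLAG-MSI2 and 677 peaks in 535 genes were lower at an adjusted p below 0.05; these are the higher and lower peaks below. The balance moved with the threshold, since the authors' deposited table gave 108 higher and 263 lower peaks at an adjusted p below 0.01, and 7608 higher and 2196 lower at an unadjusted p below 0.05. The 2 gene sets shared 61 genes, where 43 would be shared by independent sets. Of the higher peaks, 503 had no reads in the empty-vector library, and all 702 were above it in both replicates.

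The edgeR quasi-likelihood test on the same counts with TMM scaling called no peak at a Benjamini-Hochberg adjusted p below 0.05 (smallest 0.0635), while DESeq2 called 7 higher and 4 lower. The same edgeR test called 25 higher and 95 lower peaks with the size factors of DESeq2, and 24 higher and 158 lower with library totals alone. At an unadjusted edgeR p below 0.05 with TMM scaling, 3209 peaks were higher and 971 lower, where chance alone gives 761 in each direction. This split was 3016 higher and 1330 lower with the size factors of DESeq2, and 2299 higher and 1759 lower with library totals alone. The median log2 fold of all peaks moved with the scaling, from 0.97 to 0.84 and 0.62 in the same order, so each fold is relative to the rest of its library. The folds of edgeR and those of the authors' deposited table had a Spearman correlation of 0.993 across peaks, with the same sign at 100% of the higher and lower peaks. With 1 control library the test had 1 residual degree of freedom among samples. In simulated counts with few changed peaks, it recovered 0 of 50 peaks with a true 16-fold increase at the adjusted threshold. For a true 16-fold decrease it recovered 2 of 48. The edgeR p-values therefore rest on the spread between the 2 FLAG-MSI2 libraries, pooled with that of other peaks, and hold no spread of the control. No label says that the replicates came from separate cultures, so spread between cultures may not be covered either.

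**Figure D1:**
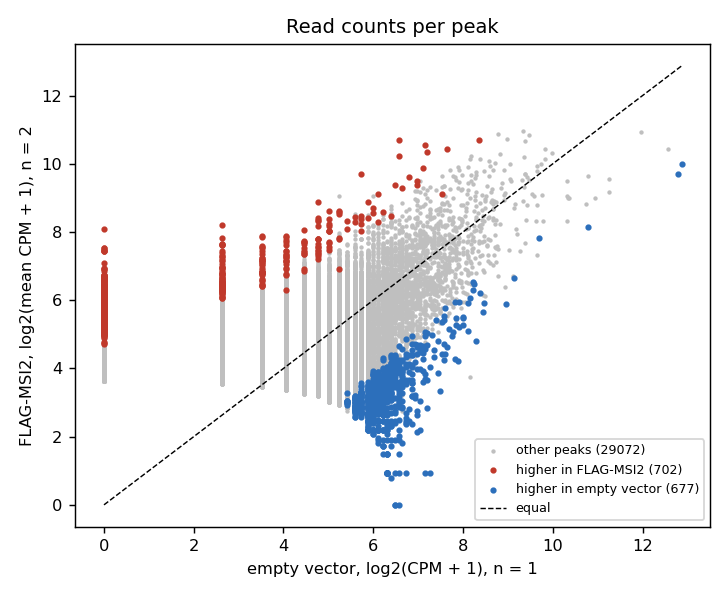
Each point is 1 peak, placed by log2(CPM + 1) in the empty-vector library and by log2 of the mean CPM + 1 of the 2 FLAG-MSI2 libraries, and the dashed line marks equal values. The 702 higher peaks (red) and the 677 lower peaks (blue) of the authors' deposited table lie on either side of the other 29072 peaks (grey), with 503 of the higher peaks at 0 CPM in the control.

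Among the higher peaks, a coding peak of RPL8 had the greatest FLAG-MSI2 signal. This peak (chromosome 8, 146016695 to 146016748 in hg19, as for all positions here) reached 1667 ± 202 CPM (SD, n = 2) against 325 CPM in the control, a log2 fold of 2.36 ± 0.74 (SE). The 3′ UTR peak of TMPO at chromosome 12, 98943133 to 98943162, had 1645 ± 80.3 CPM (SD, n = 2) against 94.2 CPM, a log2 fold of 4.12 ± 0.84 (SE). A coding peak of RPS19 (chromosome 19, 42373236 to 42373255) had 1490 ± 174 CPM against 141 CPM, and one of RPL18 (chromosome 19, 49119342 to 49119391) had 1199 ± 20.2 CPM (SD, n = 2) with a log2 fold of 3.67 ± 0.83. EEF1G, a subunit of the translation elongation factor, had 7 higher peaks, the strongest at chromosome 11, 62327226 to 62327276, with 1376 ± 48.5 CPM against 199 CPM. Coding peaks of GLTSCR2 (chromosome 19, 48258649 to 48258704) and FBL (chromosome 19, 40331367 to 40331420), both of ribosome production in the nucleolus, had log2 folds of 2.80 ± 0.80 and 3.03 ± 0.85. The growth factor MDK (chromosome 11, 46403850 to 46403899) and the tubulin TUBA1B (chromosome 12, 49521791 to 49521850) followed with log2 folds of 2.81 ± 0.81 and 2.65 ± 0.83, also in coding sequence. Peaks in 5′ UTRs included the proteasome subunit PSMA7 (chromosome 20, 60718405 to 60718436), with 714 ± 191 CPM, and the ferritin light chain FTL (chromosome 19, 49468666 to 49468718), with 662 ± 93.3 CPM (SD, n = 2). The 3′ UTR peak of the apolipoprotein APOE (chromosome 19, 45412501 to 45412554) had 557 ± 63.5 CPM against 183 CPM, and a log2 fold of 1.60 ± 0.76, while the log2 fold of this peak in the authors' deposited table was 2.53. By edgeR the adjusted p of the 702 higher peaks ran from 0.133 to 0.330, and 700 of them had an unadjusted p below 0.05. Ribosomal protein genes, EEF1G, FTL and TUBA1B have near-identical copies or pseudogenes, so the assignment of their reads to 1 locus is uncertain.

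The higher peaks with the largest folds, among those with at least 20 reads in each FLAG-MSI2 replicate, had no reads in the empty-vector library. Their folds are therefore lower bounds against 3 reads. The TMPO peak at chromosome 12, 98943207 to 98943230, was at least 16-fold higher, with 252 reads in replicate 1 and 63 in replicate 2, and the bound was 29-fold with replicate 1 alone and 5.7-fold with replicate 2 alone. CHCHD1 and MRPS16, proteins of the small mitochondrial ribosomal subunit that lie on chromosome 10, were at least 11.5-fold higher in a coding peak (75542094 to 75542152) and 10.6-fold higher in a 3′ UTR peak (75008762 to 75008783). The bound for MRPS16 was 16.9-fold with replicate 1 alone and 5.6-fold with replicate 2 alone. The translation factor EIF4H had a 3′ UTR peak (chromosome 7, 73610490 to 73610541) at least 11-fold higher, with 103 and 114 reads. MAGT1 (3′ UTR, chromosome X, 77083818 to 77083871) was at least 10.2-fold higher, with 153 and 47 reads in the replicates and bounds of 17.6-fold and 4.3-fold with each alone, and the mitochondrial protein C1QBP (coding, chromosome 17, 5341475 to 5341533) at least 10.6-fold. The antiviral membrane protein IFITM3 (coding, chromosome 11, 320740 to 320791) and GATC (3′ UTR, chromosome 12, 120898899 to 120898982) were at least 8.7-fold and 7.9-fold higher. PKM2, the pyruvate kinase of glycolysis (coding, chromosome 15, 72499531 to 72499559), and NFKBIL1 (coding, chromosome 6, 31525957 to 31526017) were at least 7.5-fold and 7.3-fold higher. SUMF2 (coding, chromosome 7, 56142331 to 56142382) and the tumour suppressor VHL (3′ UTR, chromosome 3, 10192670 to 10192707) were at least 6.9-fold and 6.5-fold higher, and the bound for VHL was 9.5-fold with replicate 1 alone and 4-fold with replicate 2 alone. In the authors' deposited table the adjusted p of these peaks ran from 0.000153 for CHCHD1 to 0.00405 for VHL.

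**Figure D2:**
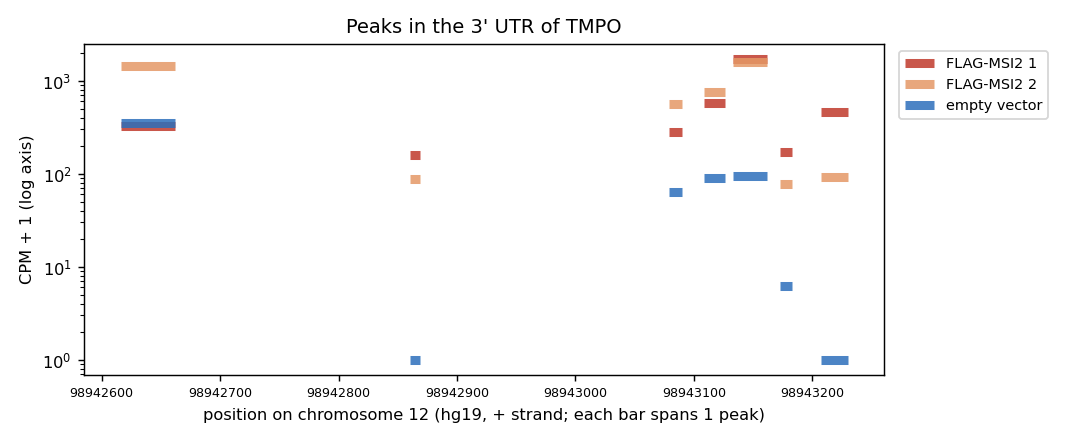
CPM + 1 (log axis) of each library at the 7 peaks of the TMPO 3′ UTR, with each bar spanning the positions of 1 peak on chromosome 12 in hg19. At 6 peaks both FLAG-MSI2 replicates lie above the empty-vector library; at the peak from 98942616 to 98942662, replicate 1 with 178 reads lies beside the control with 67 reads, and replicate 2 with 1000 reads lies above both.

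The lower peaks named here, from those with the largest folds, lay in coding sequence. TRAPPC8, a subunit of a vesicle tethering complex, had 18 reads in the empty-vector library and 0 in both FLAG-MSI2 replicates at chromosome 18, 29433817 to 29433868, at least 39.4-fold higher in the control. The zinc finger gene ZNF518A (chromosome 10, 97917235 to 97917284) had 17 control reads and no FLAG-MSI2 reads, at least 37.2-fold higher in the control. CENPF (chromosome 1, 214788173 to 214788249) and NCAPG (chromosome 4, 17826601 to 17826653) had log2 folds of -7.15 ± 1.2 and -7.04 ± 1.21 (SE), and an edgeR adjusted p of 0.0635 each; the log2 folds in the authors' deposited table were -7.80 and -7.55. PICALM, a gene of clathrin-mediated endocytosis, had 20 control reads and 1 FLAG-MSI2 read at chromosome 11, 85714435 to 85714462. The authors' deposited table gave these peaks adjusted p-values from 2.35e-09 for NCAPG to 3.92e-05 for ZNF518A.

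The second comparison asked how closely the 2 FLAG-MSI2 replicates followed each other. Reads summed per gene, over 4479 genes with at least 30 reads, had a Pearson r of 0.867 between the replicates, and 0.730 and 0.661 between replicates 1 and 2 and the empty-vector library. Per peak, r of log2(CPM + 1) was 0.368 between the replicates, 0.338 between replicate 1 and the control and 0.133 between replicate 2 and the control. Over the 12981 peaks with at least 10 reads in both replicates, r was 0.717 between the replicates, and 0.493 and 0.439 between replicates 1 and 2 and the control. Single peaks differed more: the TMPO peak from 98942616 to 98942662 had 178 reads in replicate 1 and 1000 in replicate 2, and a coding peak of TGFBR1 had 20 and 289. These correlations run across genes or peaks, which are not independent replicates, and every peak of the table had at least 16 reads summed over the libraries. The filter of 10 reads applied to the replicates and not to the control, which also had fewer reads in peaks than either. No correlation was made at equal depth, so a lower r with the control does not by itself show signal shared by the replicates.

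The third comparison asked where on transcripts the recovered regions lay, using the feature class of each peak in the authors' deposited table. Of the 702 higher peaks, 206 lay in 3′ UTRs, 29.3% (Wilson 95% interval 26.1 to 32.8), against 19.1% of all peaks and 12.3% of the lower peaks (interval 10 to 14.9). The odds of a 3′ UTR position were 1.78 times those of all other peaks (95% interval 1.51 to 2.1; two-sided Fisher's exact test, p = 4.12e-11, adjusted p = 2.47e-10 over 12 tests of feature and direction). SPN, the gene of the leukocyte surface protein CD43, held 13 of these 3′ UTR peaks, and TMPO held 6. Coding peaks made up 57.1% of the higher peaks, 60.3% of all peaks and 75.5% of the lower peaks, with an odds ratio of 2.05 for the lower peaks (1.72 to 2.45; adjusted p = 6.77e-16). Peaks in 5′ UTRs were less frequent than among the other peaks in both the higher set (10.3%, odds ratio 0.63, adjusted p = 0.000300) and the lower set (9.3%, odds ratio 0.57, adjusted p = 1.93e-05). The median log2 fold was 1.60 over the 5825 peaks in 3′ UTRs and 0.81 over the 18374 coding peaks. Reads in 3′ UTR peaks were 16.7% and 17.6% of all reads in the FLAG-MSI2 replicates and 12.6% in the empty-vector library. Peaks of 1 gene are not independent, and with 1 peak per gene the odds ratio was 2.05 (1.45 to 2.90). All these values rest on the same single empty-vector library. The tests across peaks do not cover how its share of 3′ UTR reads would vary between control libraries. At an adjusted p below 0.001 in the authors' deposited table, which left 12 higher peaks, it was 3.02 (0.96 to 9.52), and its interval included 1.

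**Figure D3:**
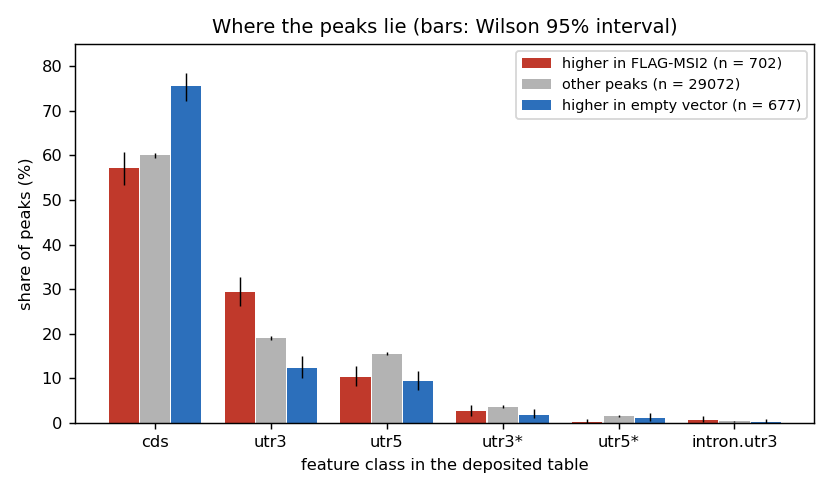
Share of peaks in each feature class of the authors' deposited table for the 702 higher, 29072 other and 677 lower peaks, with Wilson 95% intervals as bars. The 3′ UTR (utr3) holds 29.3% of the higher peaks and 12.3% of the lower peaks, and coding sequence (cds) 57.1% and 75.5%; the sources used here do not say what the star marks.

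The fourth comparison asked which gene groups the higher peaks fell in, among the 5765 genes with a peak. Of the 20 fixed lists with a member among them, glycolysis was called: 7 of its 19 genes had a higher peak, an odds ratio of 6.77 (95% interval 2.65 to 17.3; two-sided Fisher's exact test, adjusted p = 0.00884), and 7 when adjusted over the list alone. In this list HK1 had a coding peak with 379 ± 4.2 CPM (SD, n = 2) and a log2 fold of 2.59 ± 0.85, and PKM2 had 3 higher peaks. A lower peak was found in 4 of the 19 genes, among them PKM2 and ENO1. A coding peak of ENO1 had 53 and 52 reads against 1 control read, a ratio of 16 (95% counting interval 2.8 to 638), and a 3′ UTR peak of TPI1 was at least 3.3-fold higher. Over all peaks of each gene the log2 folds were 0.04 for ENO1 and 0.34 for TPI1, against 1.52 for HK1 and 0.86 for PKM2. Glycolysis genes carry many reads, and random lists matched on total reads held 5.3 genes with a higher peak (adjusted p = 1.00). With either FLAG-MSI2 replicate left out and as many peaks ranked by fold, the odds ratio was 3.39 without replicate 1 and 3.52 without replicate 2, and the adjusted p was 0.596 and 0.429.

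The counts of higher genes in the other lists did not pass Fisher's exact test (adjusted p between 0.309 and 1.00). The values against matched random lists control for the read number of the genes and not for their number of peaks. Of 76 cytosolic ribosomal protein genes, 10 had a higher peak (11 adjusted over the list alone), led by RPL8, RPS19, RPL18 and RPL7A, while matched random lists held 25.2 (adjusted p = 0.00400). Without matching, the odds ratio of this list was 1.75 (95% interval 0.89 to 3.43). Of its 574 peaks 13 were higher, a share like that of all peaks (702 of 30451). These peaks held 7.35% and 5.96% of the reads of FLAG-MSI2 replicates 1 and 2 and 7.22% of those of the control. No test matched both reads and number of peaks, so a shortfall beyond the number of peaks per gene was neither shown nor excluded. Chromatin regulators and replication-dependent histones had 0 of 43 and 0 of 19 genes (0 and 0 adjusted over the list alone), where matched lists held 5.4 and 5.6 (adjusted p = 0.0187 and 0.0180). Against matched lists, the chromatin list did not pass without replicate 1 (2 genes, adjusted p = 0.410) or without replicate 2 (3 genes, 0.851), nor at an unadjusted edgeR p below 0.05, where it had 19 genes against 17.2 (0.963). The histone list also did not pass without replicate 1 (adjusted p = 0.0560) or without replicate 2 (0.370), while the ribosomal protein list passed in both (0.00400 each). The ribosomal count fell to 4 genes against 21.3 without replicate 1, and to 5 against 22.9 without replicate 2. The histone list passed with peaks ranked by the fold of both replicates (0 against 5.6, adjusted p = 0.0180). At an unadjusted edgeR p below 0.05 it also passed (3 against 12.3, adjusted p = 0.00200). It did not pass with 3′ UTR peaks only (0 against 1.9) or at the authors' adjusted p below 0.001 (0 against 0.1). Translation factors had 7 of 41 genes (11 adjusted over the list alone), among them EEF1G, EIF4H, the poly(A)-binding protein PABPC1 and EIF3A. A 5′ UTR peak of PABPC1 had a log2 fold of 2.39 ± 0.84 and a coding peak of EIF3A 3.03 ± 0.96. Over all peaks of these 2 genes the log2 folds were 0.744 and 0.852. RNA-binding proteins and splicing factors had 7 of 54 (9 adjusted over the list alone). Single peaks of HNRNPA0, TARDBP and PCBP1 had log2 folds of 2.93 ± 0.90, 3.03 ± 1.00 and 2.75 ± 0.97, and 1 of HNRNPAB had a ratio of 17.5 (3.1 to 698). Over all peaks of each gene the log2 folds were 1.498, 1.705, 1.009 and 0.489 in the same order. With replicates 1 and 2 alone the ratio at the single peak was 12.4 and 4.1 for TARDBP and 10 and 23.5 for HNRNPAB. The cell cycle list had 4 of 38 (5 adjusted over the list alone). The higher peaks of MCM4, CCNA2 and MCM2 had no control reads, and that of MCM7 had a ratio of 17.8 (3.1 to 710). Over all peaks of each gene the log2 folds were 0.265 for MCM4, 1.464 for CCNA2, 0.562 for MCM2 and 0.41 for MCM7. At an unadjusted edgeR p below 0.05 this list had 18 genes against 10.9 in matched lists (adjusted p = 0.0467), and it did not pass in the other settings (adjusted p between 0.851 and 1.00). Oxidative phosphorylation had 2 of 65 (ATP5G3 and SDHA; 6 adjusted over the list alone), erythroid genes 2 of 18 (FTL and GYPC; 5 adjusted over the list alone), and haematopoietic and leukaemia regulators 2 of 23 (STAT5A and BCR; 0 adjusted over the list alone). Over all peaks of each gene the FLAG-MSI2 to control ratio was 2.00 (95% counting interval 1.60 to 2.52) for STAT5A and 0.87 (0.78 to 0.97) for BCR. In that list 4 other genes (KLF1, MYB, MYC and STAT5B) had a lower peak, though the ratio over all peaks of STAT5B was 2.56 (1.94 to 3.45). Ubiquitin ligase machinery had 2 of 20 (HUWE1 and UBE2K; 1 adjusted over the list alone) and Wnt signalling 1 of 16 (DVL1; 0 adjusted over the list alone). No gene had a higher peak, with or without adjustment over the list alone, in TGF-beta and BMP signalling (21 genes), Notch signalling (11), reported Musashi targets (10), or the megakaryocyte (3), myeloid (1), lymphoid (1) and structural noncoding RNA (1) lists. At an unadjusted edgeR p below 0.05 the first 3 of these had 9, 1 and 5 genes against 5.6, 2.2 and 3.3 in matched lists. None of the 3 passed (adjusted p between 0.339 and 0.963). Mitochondrially encoded RNAs had no peak. Some named genes with a higher peak also had lower peaks, with 2 in PABPC1 and 1 each in EIF3A, HNRNPA0, MCM4, ATP5G3, DVL1, HUWE1 and VHL. Lower peaks were found in 8 chromatin regulators, 5 cell cycle genes and 3 histones.

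**Figure D4:**
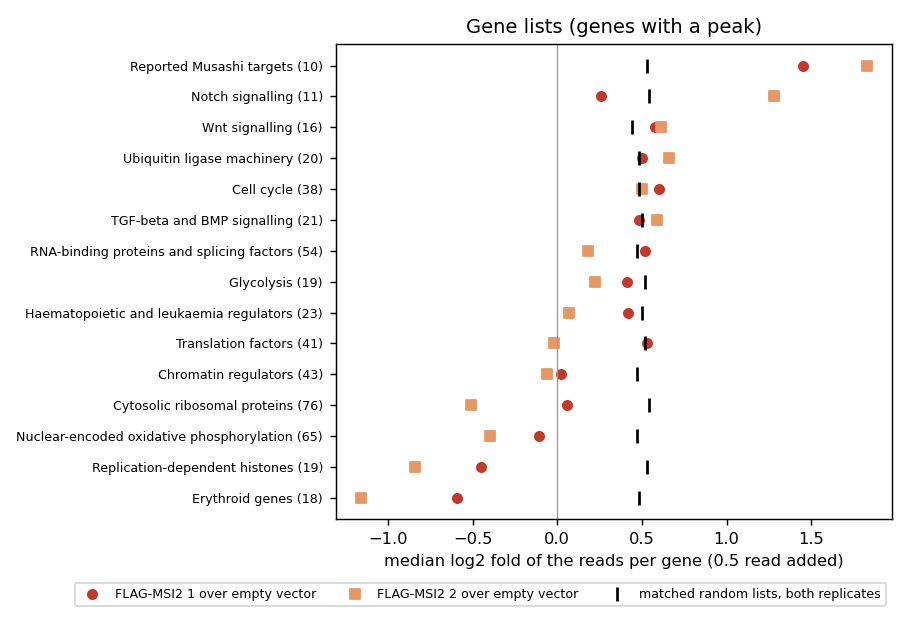
Median log2 fold over the empty-vector library of the reads summed per gene, for each FLAG-MSI2 replicate (circles, squares) and each list shown, with at least 5 genes with a peak and 0.5 read added; vertical ticks give the mean of matched random lists for both replicates together. The erythroid list lies lowest (-0.59 and -1.16) and the reported Musashi targets highest (1.45 and 1.83), though that last median falls to 0.73 and 0.90 with the 3 genes without control reads set to their bound.

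The last comparison looked at MSI2 itself and at genes named in advance. MSI2 had 0 peaks, so the table gave no read of the expressed vector with which to check the labels, and NUMB, HOXA9 and IKZF2 also had 0. TGFBR1, a TGF-beta receptor, had 3 peaks with 60 and 350 reads in the FLAG-MSI2 replicates and 6 in the control, a ratio of 10.4 (95% counting interval 4.74 to 28.5). Replicate 2 carried most of it, since the ratio was 3.45 for replicate 1 and 15.9 for replicate 2. No TGFBR1 peak was among the higher peaks, with an adjusted p between 0.124 and 0.306 in the authors' deposited table. The edgeR adjusted p, between 0.309 and 0.330, does not set these peaks apart, since that of the 702 higher peaks ran from 0.133 to 0.330. SMAD3, which carries the TGF-beta signal to the nucleus, had 7 peaks and a ratio of 1.64 (1.03 to 2.74). MYC had 12 peaks and a ratio of 0.68 (0.56 to 0.83), and 2 of its coding peaks (chromosome 8, 128752745 to 128752779 and 128753173 to 128753220) were lower in the authors' deposited table. Its peaks went both ways: a 5′ UTR peak (128748318 to 128748367) had 40 and 33 reads against 1 control read. The ratio there was 11.1 (1.9 to 445), and the peak was not called (adjusted p = 0.0878 in the authors' deposited table). CDKN1A had 1 coding peak with 10 reads in each replicate and 0 in the control, a level that 3 control reads would equal. The TGF-beta list, TGFBR1 and SMAD3 were chosen from what is known of the study of these libraries, so their counts are not independent evidence.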

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

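The unadjusted edgeR count, the authors' adjusted p of 0.05, the gene-level and 100-read correlations, and the stratified, 1-peak-per-gene, wider-class and rank-based odds ratios, and matched lists under other sources of calls, were chosen after seeing the data. No paired analysis was possible because there is 1 control library, so the groups share fewer than 2 replicate numbers. The motif test and its alternatives in window, flank, shuffling, threshold and replicate were not run. Using all peaks of the table leaves no other peaks to compare, so it gives no odds ratio. Leaving out a FLAG-MSI2 replicate leaves 1 library against 1, with no residual degree of freedom, so the per-peak test has no such value.

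Against 0 calls by edgeR with TMM scaling, size factors of DESeq2 gave 120 peaks (25 higher), library totals 182 (24 higher) and the DESeq2 Wald test 11 (7 higher), with 28928 adjusted p-values left as NA. An unadjusted p below 0.05 gave 4180. The authors' deposited table gave 1379 peaks below 0.05 (50.9% higher), 371 below 0.01 (29.1% higher) and 91 below 0.001 (13.2% higher). A minimum of 30 reads gave 0. A 4-fold minimum also gave 0, as it must where no peak was called. No count filter gave 0 too, but the filter removed no peak. The cause of the difference between scalings was not tested.

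Per peak, r between the replicates was 0.258 with a pseudocount of 0.1, 0.491 with 5, 0.717 with 10 reads in both replicates, 0.516 with 100 summed reads and 0.867 per gene, against 0.368. The 3′ UTR odds ratio kept its direction and its side of the threshold, between 1.53 and 2.12, in all alternatives run except an adjusted p below 0.001 (3.02, with 12 higher peaks). All of these alternatives used the same single control library. Rankings without replicate 1 or without replicate 2 gave 1.53 and 1.86, and the 2 rankings of 702 peaks shared 242. The 1 called list, glycolysis, was called again with the edgeR unadjusted p. It was also called with the 4-fold minimum, but that minimum left the values of every list unchanged. The number of called lists was 0 with an adjusted p below 0.001, with 3′ UTR peaks alone, without replicate 1, without replicate 2, and with peaks ranked by the fold of both; it was 3 with matching on total reads, which were other lists (ribosomal proteins, chromatin regulators, histones), all below their matched number. Under other sources of calls, the chromatin list turned to 19 genes against 17.2 at the edgeR unadjusted p, and the ribosomal list to 1 gene against 0.6 at an adjusted p below 0.001. The cell cycle list was called above its matched number at the edgeR unadjusted p alone (18 against 10.9). The cause was not tested. MSI2 had 0 peaks under every setting, since none changes the list. At the control's depth, 15.7 CPM is the lowest level that 3 reads can show.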

Other observations

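In this part the list medians, the list tests for lower peaks, the tests of symbol stems, trinucleotides and the ApA column, the thinned libraries, the scaling test and the genes named outside the fixed rule (among them the globin, ribosomal protein and histone genes, FASN, SPN, ARID3A, LINC00273, MTRNR2L2 and NEMF) were chosen only after the results had been seen. Earlier tests of the lower peaks were set aside, since they were fixed by the minimum of 16 summed reads, ran on peaks picked for their fold, set lower peaks against chance or compared unadjusted with adjusted calls.

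Several gene groups had fewer reads with FLAG-MSI2, relative to the control, than genes of like read number. The erythroid list had 8 of 18 genes with a lower peak (11 adjusted over the list alone), an odds ratio of 7.92 (Fisher's exact test, adjusted p = 0.000986), and matched random lists held 2.6 (adjusted p = 0.0480). The globin genes HBG1 and HBG2 had FLAG-MSI2 to control ratios of 0.25 (95% counting interval 0.21 to 0.29) and 0.20 (0.17 to 0.24). HBZ had 0.27 (0.20 to 0.37) and HBA1 and HBA2 had 0.42 each, while the ferritin genes FTL and FTH1 had 2.42 (2.18 to 2.69) and 1.69 (1.53 to 1.89). HBG1 and HBG2, like HBA1 and HBA2, are near-identical copies, so the split of reads within each pair is uncertain. HBG1 and HBG2 both count among the 8 erythroid genes with a lower peak, so the list tests treat them as separate genes. The median log2 fold of the erythroid list was -0.79 against 0.48 in matched lists (adjusted p = 0.00160 over 16 lists), and it was -0.59 with replicate 1 alone and -1.16 with replicate 2 alone. Cytosolic ribosomal protein genes had -0.26 against 0.54, oxidative phosphorylation genes -0.29 against 0.47 and replication-dependent histones -0.67 against 0.53 (adjusted p = 0.00107 each, from the smallest p that the random lists can give). With replicates 1 and 2 alone these medians were 0.06 and -0.51, -0.11 and -0.40, and -0.45 and -0.84 in the same order. RPS15A and RPS29 had ratios of 0.19 (0.14 to 0.27) and 0.25 (0.21 to 0.31; 0.13 with replicate 1 alone and 0.34 with replicate 2 alone), ATP5E had 0.18 (0.12 to 0.27), and the linker histone HIST1H1C had 0.43 (0.40 to 0.46). With replicate 1 alone and genes without control reads at their bound, the oxidative phosphorylation list did not pass (adjusted p = 0.0856). The sign of a median near 0 depends on the scaling, and for the ribosomal protein genes also on the replicate, with its adjusted p at 0.00107 with replicate 1 alone and 0.0008 with replicate 2 alone. Lower peaks were also found by Fisher's exact test in 19 of 76 ribosomal protein genes (23 adjusted over the list alone; adjusted p = 0.000870), 13 of 65 oxidative phosphorylation genes (14; 0.0380), 12 of 54 RNA-binding protein genes (16; 0.0218) and 9 of 41 translation factor genes (10; 0.0449). Against lists matched on total reads these did not pass (adjusted p = 0.949, 0.182, 0.683 and 0.949).

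The genes with the most higher peaks were FASN, the fatty acid synthase, with 18 of its 107 peaks, SPN with 13 of 80, all in its 3′ UTR, and the transcription factor ARID3A with 8 of 37. Of the ARID3A peaks, 7 were in the class that the authors' deposited table marks with a star beside the 3′ UTR. Of all 18 higher peaks of that class, 14 were TRUE in the ApA column, against 501 of 1086 (Fisher's exact test, adjusted p = 0.0157 over 2 tests), but without ARID3A the count was 7 of 11 (p = 0.239). The meaning of that column is not given in the sources used here. Among 74 symbol stems none passed Fisher's exact test, where MCM with 4 of 8 genes with a higher peak and ZNF with 1 of 112 came closest (adjusted p = 0.0819 each). Against lists matched on total reads the HIST stem passed, with 0 of 43 genes where matched lists held 8.1 (adjusted p = 0.0148), and MCM and ZNF did not (adjusted p = 1.00 each); other sources of calls were not tried for stems. In the control, 2 peaks each of LINC00273, MTRNR2L2 and NEMF, which the authors' deposited table classes as 5′ UTR or with a star beside it, together held 3.41% of all reads, against 0.54% and 0.58% in FLAG-MSI2 replicates 1 and 2. MTRNR2L2 resembles mitochondrial ribosomal RNA, so its reads can come from that RNA.

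Genes reported as Musashi targets, 10 of them with a peak, had a median log2 fold of 1.89 against 0.53 in matched lists (adjusted p = 0.0243 over 16 lists), with replicate 1 alone 1.45 (adjusted p = 0.0742) and with replicate 2 alone 1.83 (adjusted p = 0.0288). With the 3 genes without control reads (CDKN1A, CDKN1C, TSPAN3) set to their bound of 3 reads, the median was 0.85 against 0.27 (adjusted p = 0.233), so the call rests on genes of few reads. The planned Fisher test found 0 of the 10 genes with a higher peak. Without TGFBR1 and SMAD3, which the study itself names, the median was 1.89 against 0.57 (random-list permutation p = 0.0322) and 0.50 against 0.23 at the bound (permutation p = 0.396). CCND2 and BMPR1A had ratios of 4.57 (1.92 to 14.3) and 3.70 (1.40 to 13.8), and MYC was below the control at 0.68.

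The excess of 3′ UTR peaks among the higher peaks was weighed against read depth and against genes with many peaks. Stratified by deciles of total reads the odds ratio was 2.12 (1.78 to 2.52), and with 1 peak per gene it was 2.05 (1.45 to 2.90), which argues against either as the whole cause. A candidate explanation is binding to UAG, the core of the known Musashi motif; 3′ UTRs with a higher peak (141 genes) held 8.53 UAG per kilobase against 9.26 in the others, a difference of -0.73 (-1.46 to -0.01; permutation p = 0.0760), opposite to that prediction. That interval met the bound set in advance against this explanation, but the bound was wrong, as was seen only after the result: these 3′ UTRs had less A and U (47.9% against 49.9%), all 6 trinucleotides with 1 A, 1 G and 1 U were rarer, and with AU content, length and reads in the model the difference was -0.25 (-0.89 to 0.38). UAG binding stays open, since a whole 3′ UTR is a coarse measure of a peak of 51 bases.

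The lower peaks of the authors' deposited table were 677 against 702 higher at an adjusted p below 0.05, a balance set by the threshold, since the numbers were 263 against 108 below 0.01 and 79 against 12 below 0.001. When FLAG-MSI2 replicate 1 was thinned to the control's reads, exact binomial tests at an adjusted p below 0.05 called it higher than replicate 2 at 791 peaks, against 2170 for the control; for replicate 2 against replicate 1 the numbers were 580 and 2000, which argues against counting error at the control's depth and the spread of these replicates as the whole cause of the lower peaks. The control was also called lower at more peaks than a thinned replicate was, so it differed more in both directions. The binomial tests compared single libraries in pairs and did not run on the 677 lower peaks as such. Duplicate reads in a control library of lower complexity stay open, since these tests treat reads as independent and a thinned replicate keeps its own complexity. Among the 1379 peaks of smallest edgeR p, as many as the authors' deposited table calls, the share higher was 69.1%, 56.9% and 39.2% with TMM, DESeq2 size factors and library totals, a range of 29.9 percentage points around the 50.9% of that table, so the scaling stays open as a part of the balance. The control may differ from the FLAG-MSI2 libraries in background RNA or in its culture, which a single control library leaves open, and no biological explanation was tested.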
